A study of Mus musculus with 32 samples.

How the data were processed

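Illumina and nanopore libraries were made from RNA of sorted mouse splenic B cells, 4 subsets with 4 biological replicates each, and each RNA was divided between both platforms. Per the labels, T1 cells were sorted as CD19+ CD93+ IgM+ CD23-, T2 cells as CD19+ CD93+ IgM+ CD23+, MZ cells as CD19+ CD93- CD21+ CD23- and FoB cells as CD19+ CD93- CD21- CD23+, after an enrichment of B cells by negative selection. Short-read libraries were built from amplified full-length cDNA with a SMART-Seq v4 and a Nextera XT kit and read as single ends of 50 bases. The submitters' processing notes name Trim Galore, HISAT2 2.1.0 and StringTie 2.1.1 with GRCm38. The authors deposited a table per library of coverage (signal, mean reads per base), FPKM and TPM for 52636 genes. TPM summed to 1000000 in every library, 10 to 18 repeated gene identifiers per table were summed, and 52489 identifiers were found in the GENCODE M21 annotation, 49995 of them with the same start and end. The annotation version and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands can be mixed. Long-read cDNA was amplified by PCR and read on a MinION, and the notes name minimap2 2.17-r941. The authors deposited 1 table of whole-number counts for 11728 genes in all 16 long-read libraries, of which 11593 are also listed in the short-read tables. The counting tool, the annotation and any definition of full-length reads are not given in the sources used here.

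Short-read depth was read from the ratio of coverage to FPKM of genes with a coverage of at least 5, which gave 596 to 1012 megabases of aligned reads per library. Long-read totals were 244976 to 538293 counts per library, 5908974 in all. Libraries of a subset were compared pairwise to look for a library deposited under 2 names; the long-read counts of the closest pair differed by a chi-square of 2.16 per degree of freedom, so all were kept as separate replicates.

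TPM values were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a trended and robust variance, over genes with TPM of at least 1 in at least 4 of 16 libraries (16574 genes), all 4 subsets sharing 1 fit. The contrasts were T2 against T1, MZ against T2, FoB against T2 and MZ against FoB, and a moderated F test covered all subsets. Long-read counts were tested with the quasi-likelihood test of edgeR 4.0.16 (robust, TMM normalization, filterByExpr, 5636 genes). P-values were adjusted by the Benjamini-Hochberg method within each contrast, at a threshold of 0.05. Replicate numbers were not used to pair samples, except in the alternative with a replicate block. Shares of TPM were compared by two-sided exact permutation tests, 8 in all, and the mitochondrial share also with immunoglobulin genes left out of the total, chosen after the data were seen.

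Lists of genes were fixed with their members and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 104 tests of 26 of the 28 lists, those with at least 5 measured members. The lists held the sort genes, immature B cell genes, marginal zone genes, follicular genes, ribosome assembly factors, cytosolic ribosomal proteins, endoplasmic reticulum folding, interferon-stimulated genes, sterol synthesis, oxidative phosphorylation, glycolysis, amino acid transport and mTORC1, DNA replication, mitosis, immediate early genes, innate sensing, migration and adhesion, apoptosis and survival, B cell receptor signalling, antigen presentation, RNA decay, immunoglobulin constant regions with Jchain, and markers of T cells, NK cells, monocytes with macrophages and dendritic cells, neutrophils, erythroid cells with platelets, and antibody-secreting, B-1 and germinal centre cells. Named genes were, per contrast, the 10 largest increases and 10 largest decreases among genes with an adjusted p under 0.05, a mean TPM of at least 10 in the higher group and all 4 libraries of one group above all 4 of the other. Sort genes, immunoglobulin and T cell receptor segments and unnamed gene models were left out of that choice, and to it were added the 5 sort genes and up to 4 members of each list with the smallest adjusted p. Grouping, tests, contrasts, lists, the rule for named genes and the alternatives, apart from those said to be added later, were fixed before the data were examined.

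Alternatives were a pseudocount of 0.1, other filters on low values, FPKM, median-ratio scaling, removal of immunoglobulin genes, no trend or robust variance, a replicate block, fits of 2 groups only, leaving out each library or the female replicate of every subset, DESeq2 1.42.0, DESeq2 size factors, an estimated correlation or fry for the lists, and long reads for the lists. Both tests were tested on simulated data with known changes. In each comparison 67, 67 and 66 genes were changed, by 1.5-fold, 2-fold and 4-fold. Recovery depends on the number of changed genes. The rates below therefore hold for that number and need not carry over to the data. At 1.5-fold limma recovered 35.8% to 50.7% of changed genes, at 2-fold 62.7% to 74.6% and at 4-fold 74.2% to 87.9%, with 5 to 10 false calls of 16574 genes. edgeR recovered 1.5% to 7.5%, 22.4% to 28.4% and 74.2% to 81.8%. Camera found 10 of 10 shifted lists and called 5 of 200 unchanged lists at an unadjusted p under 0.05. The simulated genes varied independently of each other, so this gives no rate of false calls for lists whose members move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. P-values measure the spread between mice of 1 strain and age.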

Results

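RNA was measured in 4 splenic B cell subsets of untreated 12-week-old C57BL/6 mice. The subsets were transitional type 1 (T1) and type 2 (T2) cells, the earlier and later immature stages that reach the spleen, and the mature marginal zone (MZ) and follicular (FoB) cells. Each subset had 4 biological replicates, 3 from male and 1 (replicate 3) from female mice, and each RNA sample was divided between Illumina short reads and nanopore long reads, for 32 libraries. Short-read expression was given in TPM, which scales every library to the same total of transcripts, and its depth, read from the ratio of coverage to FPKM, was 596 to 1012 megabases of aligned 50-base reads per library. The long-read counts summed to between 244976 and 538293 per library over 11728 genes. TPM values below are means ± SD (n = 4 libraries per subset), and log2 fold changes are on the log2(TPM + 1) scale ± SE, which understates the change of genes with low TPM. Adjusted p-values are from limma for the short reads and edgeR for the long reads. Coordinates are of GRCm38.

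The genes of the 5 surface proteins used for the sort were read as a check of the labels, since the cells had been gated on these proteins. Cd93 stood at 13.7 ± 1.1 TPM in T1 and 9.77 ± 0.41 in T2, against 0.194 ± 0.15 in MZ and 1.09 ± 0.29 in FoB. Fcer2a, which encodes CD23, stood at 202 ± 63.7 TPM in T1, 1780 ± 136 in T2, 109 ± 8.88 in MZ and 1844 ± 174 in FoB. Cr2, which encodes CD21, rose from 137 ± 16.5 TPM in T1 to 417 ± 10.4 in T2, and was 2108 ± 148 in MZ and 500 ± 67.5 in FoB. Ighm, although T1 and T2 were both gated on IgM, stood at 31850 ± 5592 TPM in T1 and 10700 ± 41.4 in T2, against 9308 ± 602 in MZ and 7089 ± 340 in FoB. Cd19 lay between 1973 ± 103 and 2374 ± 136 TPM in every subset. Xist was above 40 TPM only in replicate 3 of each subset, the libraries labelled female.

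**Figure D1:**
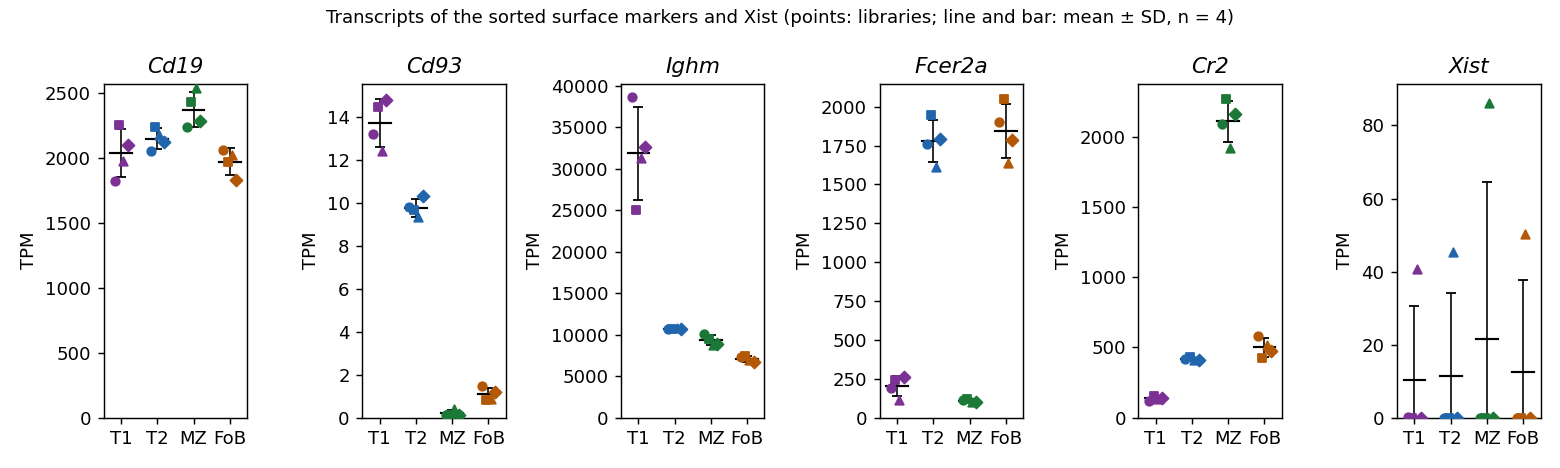
TPM of the 5 sort genes and of Xist in each of the 16 short-read libraries, one point per library, with the mean and SD of each subset. Fcer2a separates T2 and FoB (1780 and 1844 TPM on average) from T1 and MZ (202 and 109), and Xist is seen in replicate 3 of every subset.

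The subsets differed over most of the transcriptome. Of 16574 genes tested, 10216 (61.6%) differed among the 4 subsets by a moderated F test. The first principal component (40.8% of the variance) ran from T1 through T2 and FoB to MZ, and the second (20.3%) set T1 and MZ against T2 and FoB. Across genes, log2 expression of short-read libraries of the same subset correlated at r = 0.973 to 0.986, and of long-read libraries at 0.801 to 0.935. Replicate 3, from the female mice, differed from the male replicates in 2050 genes over all subsets, 1984 of them autosomal. Without the female replicate of every subset the counts of changed genes were 4836 for T2 against T1, 5593 for MZ against T2, 1066 for FoB against T2 and 5299 for MZ against FoB.

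**Figure D2:**
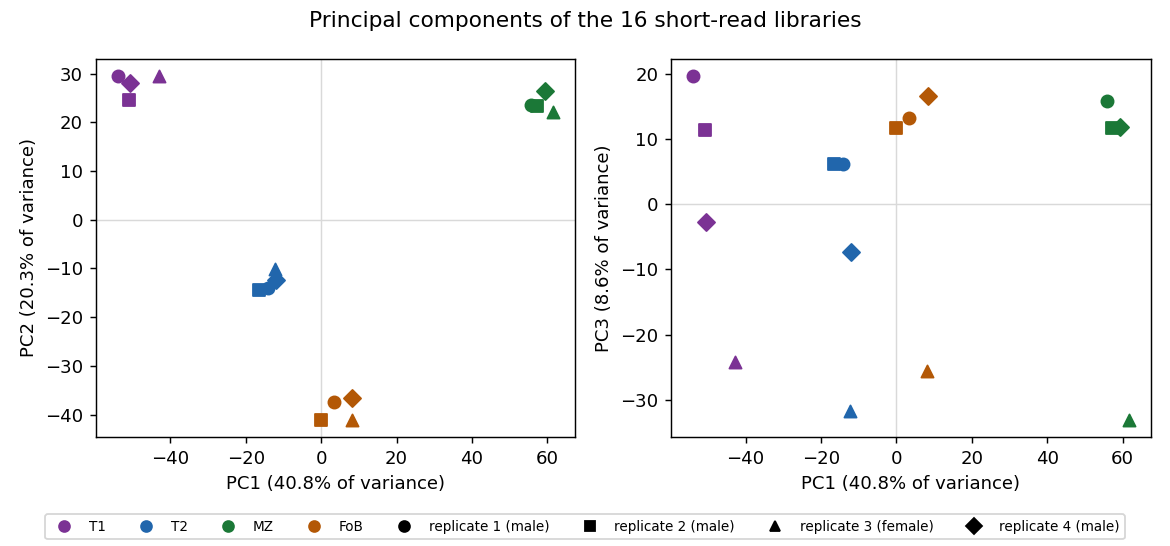
Principal components of log2(TPM + 1) over the tested genes in the 16 short-read libraries, component 1 (40.8% of the variance) against component 2 (20.3%) and component 3 (8.6%), with colour for the subset and marker for the replicate number. Libraries group by subset on components 1 and 2.

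T2 was set against T1 to ask what changes between the earlier and the later transitional stage. T2 cells held more Gimap4, a GTPase of lymphocytes, at 377 ± 25.9 against 50.8 ± 5.75 TPM (ENSMUSG00000054435, chromosome 6, 48684549 to 48692060). They also held more Ccr6, the receptor of the chemokine CCL20, at 111 ± 10.3 against 21.2 ± 2.57 TPM, and more Sell, the homing receptor L-selectin, at 752 ± 55.8 against 211 ± 37.2 TPM. T1 libraries held more Jchain, the joining chain of secreted antibody, at 119 ± 74.5 against 3269 ± 1362 TPM in T2 and T1 (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891). T1 libraries also held more transcripts of mitosis, among them Mki67 at 3.15 ± 0.566 against 10.1 ± 1.64 TPM in T2 and T1. Each library pools the sorted cells, so the values cannot tell whether all T1 cells or a few held more of these transcripts.

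Immunoglobulin genes took 21.8 ± 4.22% of TPM in T1 and 8.70 ± 0.53% in T2 (SD, n = 4, exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 libraries can give, adjusted p = 0.0381 over 8 share tests). Because TPM has a fixed sum, this lowered the values of other genes in T1. As deposited, 5461 genes changed, 4527 of them higher in T2. Removing the immunoglobulin genes and rescaling moved the median log2 fold change by -0.208, and median-ratio scaling moved it by -0.212. With immunoglobulin genes removed 3078 genes changed, 1510 higher and 1568 lower, of which 2233 were also called as deposited, none with the opposite sign. Median-ratio scaling gave 3388 genes. The log2 fold changes of T2 against T1 that follow, except those of immunoglobulin genes, are relative to this shift, from the fit without immunoglobulin genes, while TPM values are as deposited. List p-values are from the values as deposited. Among lists of at least 5 members under the alternative, neither median-ratio scaling nor removal of immunoglobulin genes changed a list call of T2 against T1. Camera compares a list with the other genes, so a shift shared by most genes could hardly change these calls. Member counts did change, for oxidative phosphorylation from 22 higher and 0 lower to 0 higher and 2 lower with immunoglobulin genes removed.

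The largest increases from T1 to T2 were in Rflnb, an actin regulator, with a log2 fold change of 3.15 ± 0.13, Gimap4 with 2.66 ± 0.08, and Rapgef4, a cAMP-activated exchange factor, with 2.47 ± 0.15. Stat4, a transcription factor of cytokine receptors, rose by 2.42 ± 0.12, Ccr6 by 2.13 ± 0.08, and the MAP kinase phosphatase gene Dusp4 by 2.13 ± 0.30. Pcp4, Crisp3, Pglyrp2 and Fxyd5 rose by 2.31 ± 0.30, 2.31 ± 0.27, 2.19 ± 0.11 and 2.03 ± 0.14. The highest adjusted p among these 10 genes was 9.81e-05. In the long reads Gimap4, Rapgef4, Stat4 and Ccr6 rose by 2.41 ± 0.28, 4.46 ± 0.47, 2.77 ± 0.38 and 1.75 ± 0.30 on the log2 scale. The largest decreases were in Jchain (-5.12 ± 0.73, adjusted p = 0.000197; -4.92 ± 0.41 in the long reads), Prg2 (-4.63 ± 0.37), Col5a3 (-3.56 ± 0.18), Chst1 (-3.45 ± 0.25) and the protease inhibitor gene Slpi (-3.07 ± 0.38). Map2, Fam46c, Pde4c and Wfdc21 changed by -2.97 ± 0.18, -2.86 ± 0.59, -2.78 ± 0.15 and -2.60 ± 0.09. A further gene model named Sept2, beside the main one, read 22.4 to 31.2 TPM in the T1 libraries and was listed at 0 in every T2 library, in 2 of the MZ and in 2 of the FoB libraries.

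Cell cycle transcripts fell. In the mitosis list 0 of 30 measured members rose and 27 fell relative to the shift (0 and 25 as deposited, 0 and 26 adjusted over the list alone), with adjusted p = 1.23e-29 and adjusted p = 0.0367 with an estimated correlation. Kif11, a spindle motor, changed by -1.74 ± 0.15, Mki67 by -1.64 ± 0.16, and the cyclin genes Ccnb2 and Ccna2 by -1.73 ± 0.17 and -1.68 ± 0.17. In the list of DNA replication 0 of 28 measured members rose and 11 fell relative to the shift (3 and 6 as deposited, 3 and 5 adjusted over the list alone), with adjusted p = 0.00869 and adjusted p = 0.597 with an estimated correlation. Rrm2, Cdc6 and Mcm10 changed by -1.48 ± 0.17, -1.19 ± 0.16 and -1.19 ± 0.20, and the median of that list as deposited was 0.003, against 0.203 for all tested genes. Among genes of immature B cells, 0 of 8 measured members rose and 5 fell relative to the shift (0 and 5 as deposited, 1 and 5 adjusted over the list alone), with adjusted p = 1.22e-05 and adjusted p = 0.0184 with an estimated correlation. Vpreb3 changed by -1.34 ± 0.12, the transcription factor gene Myb by -1.25 ± 0.14 and Cd24a by -0.93 ± 0.07.

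Transcripts of the secretory pathway also fell. In the list of endoplasmic reticulum folding, 0 of 37 measured members rose and 22 fell relative to the shift (0 and 10 as deposited, 0 and 10 adjusted over the list alone), with adjusted p = 1.49e-08 and adjusted p = 0.0682 with an estimated correlation. Xbp1, the transcription factor of the unfolded protein response, changed by -0.98 ± 0.11, Edem1 by -0.92 ± 0.07, Txndc5 by -0.97 ± 0.10 and the chaperone gene Hsp90b1 by -0.72 ± 0.06. Of immunoglobulin constant region genes with Jchain, 1 of 10 rose and 4 fell as deposited (1 and 5 adjusted over the list alone), with adjusted p = 9.34e-05 and adjusted p = 0.182 with an estimated correlation. Igkc changed by -1.37 ± 0.13 and Iglc1 by -1.53 ± 0.12, and Ighd, the constant region of IgD, rose by 1.42 ± 0.13, at 2562 ± 272 against 973 ± 210 TPM, all as deposited. Markers of antibody-secreting, B-1 and germinal centre cells moved with these groups. On that list 1 of 19 measured members rose and 9 fell relative to the shift (1 and 8 as deposited, 1 and 8 adjusted over the list alone), with adjusted p = 4.65e-08 and adjusted p = 0.178 with an estimated correlation. Derl3 changed by -2.35 ± 0.18, Aicda by -2.29 ± 0.21 and Tnfrsf17, which encodes the plasma cell receptor BCMA, by -3.23 ± 0.35, whereas Bcl6 rose by 0.83 ± 0.08. Interferon-stimulated genes were lower in T2 as well: 0 of 39 measured members rose and 13 fell relative to the shift (0 and 5 as deposited, 0 and 3 adjusted over the list alone), with adjusted p = 1.39e-07 and adjusted p = 0.621 with an estimated correlation. Cmpk2, Bst2 and Ddx58 changed by -1.02 ± 0.11, -0.69 ± 0.09 and -0.67 ± 0.10.

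Genes known from recirculating follicular cells rose towards T2. On that list 11 members rose and 2 fell relative to the shift, with Ighd left out there as an immunoglobulin gene. As deposited 12 of 18 measured members rose and 0 fell (12 and 0 adjusted over the list alone), with adjusted p = 6.59e-05 and adjusted p = 0.384 with an estimated correlation. Sell rose by 1.62 ± 0.11, Icosl, a costimulatory ligand, by 1.65 ± 0.10, Zfp318 by 1.21 ± 0.12 and the integrin gene Itgb7 by 1.03 ± 0.09. In the list of antigen presentation, 10 of 25 measured members rose and 4 fell relative to the shift (14 and 2 as deposited, 15 and 2 adjusted over the list alone), with adjusted p = 0.0192 and adjusted p = 0.641 with an estimated correlation. H2-Eb1 and H2-Aa, chains of MHC class II, rose by 0.89 ± 0.08 and 0.92 ± 0.10, and H2-Oa and H2-Ob by 0.70 ± 0.06 and 0.53 ± 0.06. Of cytosolic ribosomal protein genes, 41 of 48 measured members rose and 0 fell relative to the shift (46 and 0 as deposited, 47 and 0 adjusted over the list alone), with adjusted p = 7.02e-17 and adjusted p = 0.367 with an estimated correlation. Rpl13, Rpl3, Rpl8 and Rpl14 rose by 0.57 ± 0.07, 0.52 ± 0.07, 0.53 ± 0.07 and 0.55 ± 0.07. The mitochondrial genome took 1.56 ± 0.24% of TPM in T1 and 2.20 ± 0.18% in T2 as deposited (SD, n = 4, exact permutation p = 0.0286, two-sided, adjusted p = 0.0381), but with immunoglobulin genes left out of the total it took 1.99 ± 0.29% and 2.41 ± 0.20%, and the test did not pass (p = 0.0571, adjusted p = 0.0653). Among nucleolar ribosome assembly factors, 23 of 42 measured members rose and 0 fell relative to the shift (33 and 0 as deposited, 37 and 0 adjusted over the list alone), with adjusted p = 4.65e-08 and adjusted p = 0.494 with an estimated correlation, for example Rrp12 by 0.67 ± 0.09 and Gar1 by 0.44 ± 0.09. In the glycolysis list 6 of 20 measured members rose and 1 fell relative to the shift (16 and 0 as deposited, 16 and 0 adjusted over the list alone), with adjusted p = 0.000263 and adjusted p = 0.21 with an estimated correlation. Aldoc, Slc2a3, a glucose transporter, and Ldha rose by 1.52 ± 0.18, 0.71 ± 0.10 and 0.30 ± 0.05.

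In the long reads the calls of T2 against T1 numbered 190 of 5636 genes, 50 higher and 140 lower. Immunoglobulin genes made up 110 of these, 1 higher and 109 lower, and with them removed from the library totals 57 genes were called.

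MZ was set against T2 to ask how the marginal zone fate differs from the transitional stage. MZ cells held more S1pr3, a receptor for sphingosine 1-phosphate, at 189 ± 4.55 against 9.58 ± 1.1 TPM (ENSMUSG00000067586, chromosome 13, 51408639 to 51422797). They held more Dtx1, a target of Notch signalling, at 639 ± 57.6 against 82.0 ± 9.09 TPM, and more Cd1d1, which presents lipid antigens, at 568 ± 64.2 against 110 ± 5.29 TPM. They held less Vim, an intermediate filament gene, at 14.6 ± 5.16 against 186 ± 17.6 TPM, and less Bcl6, a repressor needed for germinal centres, at 19.5 ± 1.63 against 67.6 ± 4.29 TPM. In the short reads 6326 genes changed, 3204 higher and 3122 lower, and 1399 of them by at least 2-fold on the fitted scale, 793 higher and 606 lower. In the long reads 337 genes changed, 166 higher and 171 lower.

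The largest increases were in Asb2, a ubiquitin ligase subunit (ENSMUSG00000021200, chromosome 12, 103321142 to 103356001), with a log2 fold change of 5.03 ± 0.24, Tspan15 with 4.95 ± 0.21, the lipase gene Pla2g7 with 4.90 ± 0.22 and the actin-binding gene Nebl with 4.71 ± 0.30. Serpine2, Ms4a7, Ube2e2 and the inhibitory receptor gene Lair1 rose by 4.50 ± 0.14, 4.44 ± 0.18, 4.31 ± 0.17 and 4.30 ± 0.20. Lilrb4a rose by 4.40 ± 0.36, but it has a close paralog with which short reads can be shared. Tsga13 read 23.2 to 26.8 TPM in the MZ libraries and was listed at 0 in every T2 and FoB library. The largest decreases were in Pde2a, which breaks down cyclic nucleotides (ENSMUSG00000110195, chromosome 7, 101421691 to 101512827), with -5.76 ± 0.22, Myadm with -4.59 ± 0.16, and Lef1, a transcription factor of early lymphocytes, with -4.51 ± 0.25. Jchain, Wfdc17, Atp1b1, Ly6c2, Vim and Pcp4 changed by -4.44 ± 0.71, -4.38 ± 0.35, -4.37 ± 0.11, -4.13 ± 0.36, -3.64 ± 0.18 and -3.60 ± 0.29. Wfdc21 read 25.2 to 28.9 TPM in T2 and was listed at 0 in every MZ and FoB library. The highest adjusted p among the 20 genes with the largest changes was 0.000218. The long reads gave 4.99 ± 0.93 for Asb2, 4.17 ± 0.56 for S1pr3, -6.29 ± 1.17 for Pde2a and -2.94 ± 0.43 for Vim.

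Genes known from marginal zone cells or the Notch2 pathway rose: 16 of 18 measured members rose, 1 fell and 1 did not pass (16 and 1 adjusted over the list alone), with adjusted p = 3.54e-14 and adjusted p = 0.0367 with an estimated correlation. S1pr3, Dtx1, Plxnd1 and Cd1d1 rose by 4.17 ± 0.12, 2.95 ± 0.09, 2.65 ± 0.11 and 2.35 ± 0.10. Genes known from follicular cells fell: 3 of 18 measured members rose, 13 fell and 2 did not pass (3 and 13 adjusted over the list alone), with adjusted p = 6.14e-06 and adjusted p = 0.347 with an estimated correlation. Itgb7, Cd55, S1pr4 and Cd200 changed by -1.88 ± 0.10, -1.82 ± 0.08, -1.79 ± 0.10 and -2.25 ± 0.13. Immature B cell genes fell too: 1 of 8 measured members rose, 6 fell and 1 did not pass (1 and 6 adjusted over the list alone), with adjusted p = 0.000279 and adjusted p = 0.0367 with an estimated correlation. Sox4, Vpreb3 and Myb changed by -3.55 ± 0.12, -2.85 ± 0.12 and -2.30 ± 0.14.

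Cytosolic ribosomal protein genes were higher in MZ: 46 of 48 measured members rose, 0 fell and 2 did not pass (48 and 0 adjusted over the list alone), with a median log2 fold change of 0.60, adjusted p = 5.64e-16 and adjusted p = 0.371 with an estimated correlation. Rpl13, Rpl32, Rps18 and Rpl36 rose by 0.79 ± 0.07, 0.90 ± 0.09, 0.93 ± 0.09 and 0.91 ± 0.10. Transcripts of the mitochondrial genome rose beside them, from 2.20 ± 0.18% to 3.51 ± 0.22% of TPM (SD, n = 4, exact permutation p = 0.0286, two-sided, adjusted p = 0.0381). Sterol synthesis genes fell: 0 of 24 measured members rose, 15 fell and 9 did not pass (0 and 15 adjusted over the list alone), with adjusted p = 5.12e-06 and adjusted p = 0.172 with an estimated correlation. Ldlr, the receptor for low-density lipoprotein, changed by -1.54 ± 0.13, and the enzyme genes Hmgcs1, Sqle and Fdps by -1.30 ± 0.11, -1.23 ± 0.11 and -1.01 ± 0.09. Innate sensing genes were mostly higher: 15 of 29 measured members rose, 4 fell and 10 did not pass (15 and 4 adjusted over the list alone), with adjusted p = 0.00425 and adjusted p = 0.416 with an estimated correlation. Tlr3, a sensor of double-stranded RNA, rose by 3.71 ± 0.21, Ly96, the partner of TLR4, by 1.86 ± 0.13 and Nod1 by 1.53 ± 0.12.

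Other lists did not pass in this comparison. In the mitosis list 0 of 30 measured members rose, 3 fell and 27 did not pass (0 and 3 adjusted over the list alone), with adjusted p = 0.39, and of ribosome assembly factors 2 and 4 of 42 were higher and lower (adjusted p = 0.767). Among DNA replication genes 2 of 28 measured members rose, 11 fell and 15 did not pass (2 and 14 adjusted over the list alone), with adjusted p = 0.0583, and among markers of antibody-secreting, B-1 and germinal centre cells 4 of 19 measured members rose, 9 fell and 6 did not pass (4 and 9 adjusted over the list alone), with adjusted p = 0.0873. Immediate early genes gave adjusted p = 0.25 with all libraries and adjusted p = 0.019 without MZ replicate 3 (0.00488 without replicate 3 of every subset), 4 and 10 of 34 being higher and lower over all libraries. Without MZ replicate 3 the marker list of antibody-secreting cells gave 0.049. DNA replication gave 0.0455 without T1 replicate 4, 0.0486 with median-ratio scaling and 0.0469 with immunoglobulin genes removed. Immunoglobulin constant region genes gave adjusted p = 0.0919, with 1 and 4 of 10 higher and lower, and passed without T2 replicate 3 (0.0441) and with a replicate block (0.0362). Glycolysis gave adjusted p = 0.0925, and 0.0492 without MZ replicate 4. Interferon-stimulated genes gave adjusted p = 0.556, with 9 and 5 of 39 higher and lower. Isg15 and Gbp7 rose by 2.04 ± 0.16 and 1.83 ± 0.19.

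FoB was set against T2 to ask how the follicular fate differs from the same transitional stage. FoB cells held less Myb at 1.41 ± 0.492 against 15.7 ± 1.94 TPM, less Cfp, the complement factor properdin, at 10.3 ± 2.34 against 118 ± 18.0 TPM (ENSMUSG00000001128, chromosome X, 20925454 to 20931555), and less of the mitotic gene Mki67 at 0.337 ± 0.199 against 3.15 ± 0.566 TPM. They held more Ccr6 at 259 ± 20.8 against 111 ± 10.3 TPM and more Traf1, a signalling adaptor of TNF receptors, at 104 ± 16.3 against 35.5 ± 5.93 TPM. In the short reads 1528 genes changed, 576 higher and 952 lower, and 293 of them by at least 2-fold on the fitted scale, 80 higher and 213 lower.

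The largest increases were in Mapk12, a p38 kinase gene beside Mapk11 (ENSMUSG00000022610, chromosome 15, 89130585 to 89140703), with a log2 fold change of 2.20 ± 0.13, Rhbdf1 with 2.03 ± 0.18, the polarity gene Crb3 with 1.85 ± 0.21 and the lipase-like gene Plbd1 with 1.75 ± 0.18. Apoe, a lipid carrier, rose by 1.67 ± 0.29, at 289 ± 84.6 against 88.1 ± 11.4 TPM. Il9r, Traf1, L1cam and Fam212a rose by 1.53 ± 0.31, 1.53 ± 0.16, 1.38 ± 0.18 and 1.37 ± 0.13. Il6ra, a subunit of the interleukin-6 receptor, rose by 1.53 ± 0.33, a call lost without the female replicate of every subset (1.35). The largest decreases were in Jchain, with -4.88 ± 0.71, Cfp with -3.41 ± 0.13, Ly6c2 with -3.21 ± 0.36, Myb with -2.80 ± 0.14 and Endou with -2.48 ± 0.16. Sapcd1, Eaf2, the ubiquitin ligase gene Nedd4 and Mgst1 changed by -2.46 ± 0.40, -2.46 ± 0.16, -2.34 ± 0.09 and -2.29 ± 0.15. Wfdc21 was also among these 10, at 25.2 to 28.9 TPM in T2 and listed at 0 in every FoB library. Of the 20 genes with the largest changes the highest adjusted p was 0.00805. Cfp, Nedd4 and Plbd1 also passed in the long reads, with -2.69 ± 0.28, -1.91 ± 0.38 and 2.91 ± 0.60. Long reads called 19 genes, 3 higher and 16 lower, and 7 without FoB replicate 2, 12 without T2 replicate 2 and 1 when only the libraries of T2 and FoB were fitted.

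Transcripts of mitosis fell: 0 of 30 measured members rose, 22 fell and 8 did not pass (0 and 28 adjusted over the list alone), with adjusted p = 1.03e-25 and adjusted p = 0.0367 with an estimated correlation. Top2a, Nusap1, Kif11 and Mki67 changed by -1.96 ± 0.20, -1.66 ± 0.18, -1.64 ± 0.16 and -1.64 ± 0.15. In the list of DNA replication 1 of 28 measured members rose, 8 fell and 19 did not pass (1 and 10 adjusted over the list alone), with adjusted p = 1.85e-05 and adjusted p = 0.368 with an estimated correlation. Uhrf1, Rrm2 and Mcm7 changed by -1.22 ± 0.13, -1.14 ± 0.17 and -0.46 ± 0.07. Immature B cell genes fell: 0 of 8 measured members rose, 6 fell and 2 did not pass (0 and 6 adjusted over the list alone), with adjusted p = 1.49e-08 and adjusted p = 0.00414 with an estimated correlation. Sox4, Lef1 and Cd24a changed by -2.21 ± 0.12, -2.15 ± 0.25 and -0.51 ± 0.08. Follicular genes rose: 8 of 18 measured members rose, 0 fell and 10 did not pass (8 and 0 adjusted over the list alone), with adjusted p = 0.000132 and adjusted p = 0.416 with an estimated correlation. Itgb7, Zfp318, Cd55 and Icosl rose by 0.66 ± 0.10, 0.60 ± 0.12, 0.46 ± 0.08 and 0.51 ± 0.11. Marginal zone genes fell on balance: 1 of 18 measured members rose, 7 fell and 10 did not pass (4 and 11 adjusted over the list alone), with adjusted p = 0.000856 and adjusted p = 0.416 with an estimated correlation. Plxnd1, Cd36 and S1pr3 changed by -2.12 ± 0.11, -1.26 ± 0.16 and -0.83 ± 0.12, while Dtx1 rose by 0.53 ± 0.09.

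Antigen presentation genes rose on balance: 8 of 25 measured members rose, 2 fell and 15 did not pass (8 and 2 adjusted over the list alone), with adjusted p = 0.00384 and adjusted p = 0.579 with an estimated correlation. H2-Oa and H2-DMb1 rose by 0.51 ± 0.07 and 0.49 ± 0.07, while the lysosomal genes Ifi30 and Ctsb changed by -0.87 ± 0.08 and -0.52 ± 0.07. Markers of antibody-secreting, B-1 and germinal centre cells fell: 0 of 19 measured members rose, 8 fell and 11 did not pass (0 and 9 adjusted over the list alone), with adjusted p = 2.34e-05 and adjusted p = 0.323 with an estimated correlation. Cd5, Rgs13, Bhlhe41 and Derl3 changed by -1.63 ± 0.19, -1.56 ± 0.21, -1.81 ± 0.30 and -0.95 ± 0.17. Immunoglobulin constant region genes with Jchain went the same way: 1 of 10 measured members rose, 3 fell and 6 did not pass (1 and 3 adjusted over the list alone), with adjusted p = 0.0298 and adjusted p = 0.475 with an estimated correlation. Median-ratio scaling ended that call (adjusted p = 0.0507), as did leaving out T2 replicate 1 (0.0511), T2 replicate 2 (0.0713) or FoB replicate 3 (0.0904). Iglc1 and Iglc2 changed by -1.13 ± 0.12 and -0.52 ± 0.11, and Ighd rose by 0.55 ± 0.13. The camera test also called cytosolic ribosomal protein genes (adjusted p = 0.00282; adjusted p = 0.933 with an estimated correlation) and ribosome assembly factors (adjusted p = 0.00864; adjusted p = 0.917 with an estimated correlation), but no member of either list passed on its own. Without FoB replicate 4 the first gave adjusted p = 0.571, and without T2 replicate 3 the second gave 0.183. The sort genes, gated on, gave adjusted p = 0.0318 and adjusted p = 0.288 with an estimated correlation, and missed the threshold without T2 replicate 2 (0.0609), FoB replicate 3 (0.0557) or replicate 3 of every subset (0.0585), with a pseudocount of 0.1 (0.0747) and with a replicate block (0.0608).

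MZ was set against FoB to ask how the mature subsets differ from each other. MZ cells held more S1pr3 at 189 ± 4.55 against 5.01 ± 1.25 TPM, more Tspan15 at 71.4 ± 5.01 against 0.0482 ± 0.0651 TPM and more Plxnd1, a semaphorin receptor gene, at 43.0 ± 1.86 against 0.619 ± 0.194 TPM. FoB cells held more Ighd at 648 ± 37.0 against 3741 ± 206 TPM in MZ and FoB, more Vim at 14.6 ± 5.16 against 193 ± 19.4 TPM and more Cd55, a complement regulator, at 139 ± 6.43 against 682 ± 57.0 TPM. In the short reads 5993 genes changed, 3224 higher and 2769 lower in MZ, and 1312 by at least 2-fold on the fitted scale, 831 higher and 481 lower. The long reads called 403 genes, 216 higher and 187 lower.

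The largest increases in MZ were in Tspan15, with a log2 fold change of 6.11 ± 0.21, Pla2g7 with 6.05 ± 0.22, Asb2 with 6.03 ± 0.24, Nebl with 5.64 ± 0.30 and Rgs10, a regulator of G protein signalling, with 5.63 ± 0.31. Ackr2 and Ackr3, atypical chemokine receptor genes, rose by 5.24 ± 0.23 and 5.01 ± 0.24, and Serpine2 and Ms4a7 by 5.20 ± 0.14 and 4.81 ± 0.18. S1pr3 was also among the 10 largest. The largest decreases were in Pde2a, with -5.16 ± 0.22, Wfdc17 with -5.06 ± 0.35, Myadm with -4.05 ± 0.16, Car2, a carbonic anhydrase gene, with -3.90 ± 0.19 and Vim with -3.69 ± 0.18. Crisp3, Dusp4, Mapk12, Dmwd and Kctd14 changed by -3.63 ± 0.26, -3.45 ± 0.29, -3.43 ± 0.13, -3.43 ± 0.17 and -3.37 ± 0.15. Adjusted p-values of these 20 genes reached at most 9.72e-08. In the long reads Asb2 rose by 7.23 ± 1.19, Nebl by 7.15 ± 0.65 and S1pr3 by 5.04 ± 0.61, and Vim changed by -3.07 ± 0.43.

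The lists of marginal zone and follicular genes moved apart. Of the former 15 of 18 measured members rose, 2 fell and 1 did not pass (15 and 2 adjusted over the list alone), with adjusted p = 3.54e-14 and adjusted p = 0.0367 with an estimated correlation. Plxnd1, Cd1d1 and Dtx1 rose by 4.77 ± 0.11, 2.88 ± 0.10 and 2.43 ± 0.09. Of the latter 1 of 18 measured members rose, 13 fell and 4 did not pass (2 and 13 adjusted over the list alone), with adjusted p = 3.27e-08 and adjusted p = 0.21 with an estimated correlation. Cd55, Itgb7, Ighd and Zfp318 changed by -2.28 ± 0.08, -2.54 ± 0.10, -2.53 ± 0.13 and -2.39 ± 0.12. Ribosomal protein genes were higher in MZ than in FoB as well: 45 of 48 measured members rose, 0 fell and 3 did not pass (46 and 0 adjusted over the list alone), with adjusted p = 1.62e-12 and adjusted p = 0.437 with an estimated correlation. Rplp0, Rplp1, Rpl32 and Rps18 rose by 0.74 ± 0.08, 0.88 ± 0.10, 0.77 ± 0.09 and 0.84 ± 0.09. The mitochondrial genome took 3.51 ± 0.22% of TPM in MZ and 2.24 ± 0.40% in FoB (SD, n = 4, exact permutation p = 0.0286, two-sided, adjusted p = 0.0381). Against the 2.20 ± 0.18% of T2 the FoB share did not pass (exact permutation p = 0.8857, two-sided, adjusted p = 0.886). Sterol synthesis genes were lower in MZ: 0 of 24 measured members rose, 12 fell and 12 did not pass (0 and 12 adjusted over the list alone), with adjusted p = 6.84e-05 and adjusted p = 0.21 with an estimated correlation. Ldlr, Sqle, Fdps and Srebf2 changed by -1.80 ± 0.13, -1.34 ± 0.11, -0.93 ± 0.09 and -0.83 ± 0.08.

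Mitotic transcripts were higher in MZ: 22 of 30 measured members rose, 2 fell and 6 did not pass (25 and 2 adjusted over the list alone), with adjusted p = 4.5e-08 and adjusted p = 0.36 with an estimated correlation. They were low in both subsets, with Mki67 at 3.05 ± 0.563 against 0.337 ± 0.199 TPM. Nusap1, Kif11 and Ccna2 rose by 1.65 ± 0.18, 1.56 ± 0.16 and 1.51 ± 0.17. Innate sensing genes were higher: 16 of 29 measured members rose, 5 fell and 8 did not pass (18 and 5 adjusted over the list alone), with adjusted p = 0.0102 and adjusted p = 0.484 with an estimated correlation. Tlr3, Ly96 and Nlrx1 rose by 3.35 ± 0.21, 2.26 ± 0.13 and 1.62 ± 0.15. In the glycolysis list 10 of 20 measured members rose, 1 fell and 9 did not pass (11 and 2 adjusted over the list alone), with adjusted p = 0.0375 and adjusted p = 0.494 with an estimated correlation. That call was also lost without MZ replicate 1 (adjusted p = 0.0557), FoB replicate 3 (0.0771), FoB replicate 4 (0.0507) or replicate 3 of every subset (0.0585), with a replicate block (0.0664) and in the long reads (0.737). Ldha rose by 0.41 ± 0.07. Immediate early genes gave adjusted p = 0.17 with all libraries and adjusted p = 0.00944 without MZ replicate 3 (0.00728 without replicate 3 of every subset), 4 and 8 of 34 being higher and lower over all libraries.

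**Figure D3:**
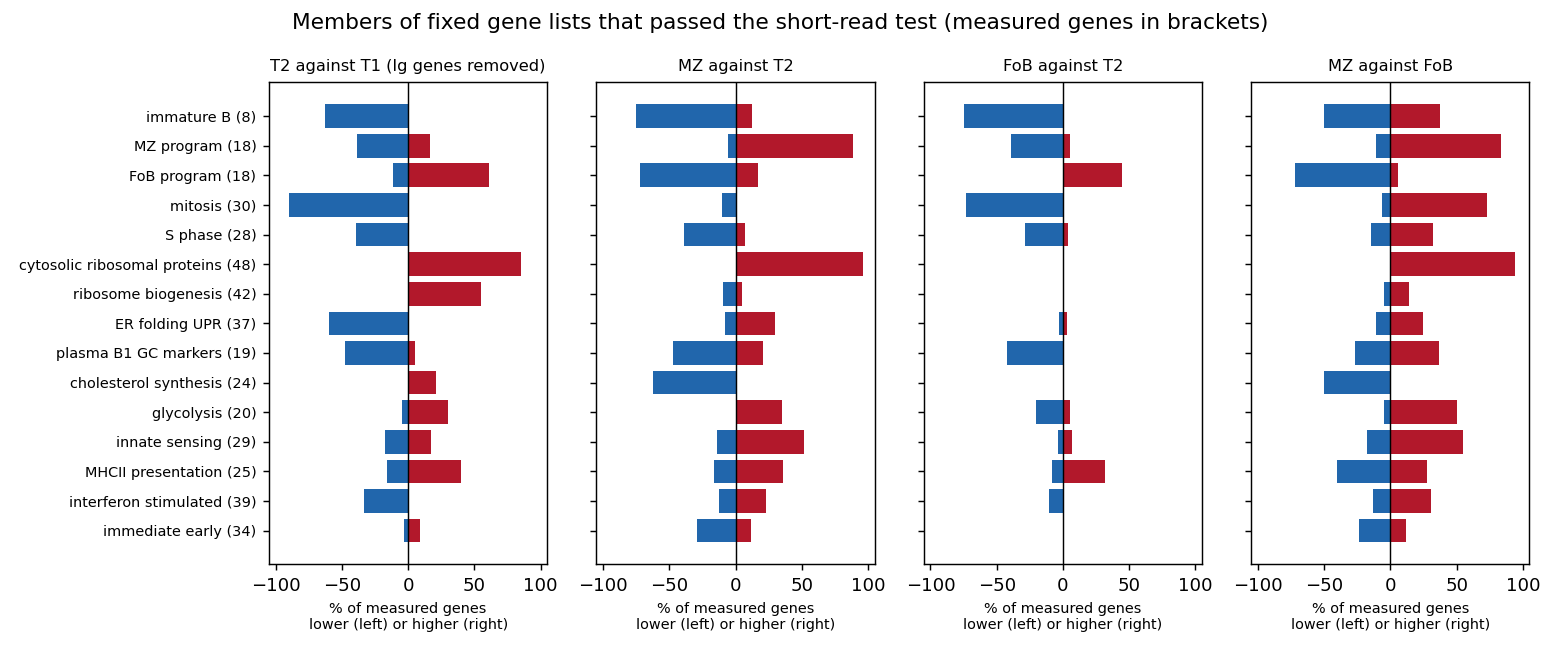
Percent of the measured members of each fixed gene list that were higher or lower at an adjusted p under 0.05 in the 4 comparisons of short-read expression, with immunoglobulin genes removed for T2 against T1. There Ighd still counts among the measured follicular genes but could not be called. Bars show the mitosis list lower in T2 against T1 and in FoB against T2, and 46 of 48 cytosolic ribosomal protein genes higher in MZ against T2.

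With all libraries and TPM as deposited, some lists passed the camera test in no comparison, and their members mostly changed in both directions. For B cell receptor signalling, the members higher and lower of 37 were 5 and 11 for T2 against T1 relative to the shift, 13 and 12 for MZ against T2, 2 and 2 for FoB against T2 and 14 and 10 for MZ against FoB (adjusted p 0.627 to 0.964). Ptpn22, a phosphatase gene, rose by 2.15 ± 0.13 in MZ against T2, and the transcription factor gene Nfatc2 by 1.48 ± 0.16 in T2 against T1. In the same order of comparisons, migration and adhesion (35 members) gave 3 and 7, 10 and 12, 2 and 6 and 11 and 10 (adjusted p 0.281 to 0.979), and apoptosis and survival (29) gave 5 and 8, 7 and 8, 3 and 2 and 9 and 7 (adjusted p 0.616 to 0.982). Gpr183, a receptor of oxysterols, rose by 1.25 ± 0.27 and the survival gene Bcl2 by 1.14 ± 0.12 in T2 against T1, and Bid, a death agonist of the BCL2 family, by 1.57 ± 0.08 in MZ against FoB. Oxidative phosphorylation (53) gave 0 and 2, 3 and 14, 0 and 1 and 7 and 3 (adjusted p 0.0873 to 0.976), after 22 and 0 as deposited in T2 against T1, a direction that rested on the scaling. That list passed in T2 against T1 without T1 replicate 2 (0.0219), and in FoB against T2 without T2 replicate 3 (0.0229), FoB replicate 2 (0.0249) or FoB replicate 4 (0.00261), or with immunoglobulin genes removed (0.0434). Amino acid transport and mTORC1 (24) gave 5 and 4, 6 and 5, 0 and 1 and 7 and 4 (adjusted p 0.458 to 0.982), regulators of RNA decay (37) gave 2 and 1, 5 and 8, 0 and 0 and 5 and 8 (adjusted p 0.135 to 0.812), and immediate early genes (34) were higher and lower in 3 and 1 for T2 against T1 and in 0 and 0 for FoB against T2. The amino acid transporter gene Slc43a1 changed by -1.75 ± 0.20 in FoB against T2. Few marker genes of other cell types were measured. Of T cell markers (5 of 18 measured) the counts were 1 and 1, 1 and 0, 1 and 0 and 1 and 1 (adjusted p 0.12 to 0.979), of monocyte, macrophage and dendritic cell markers (9 of 25) 1 and 0, 4 and 3, 2 and 3 and 5 and 2 (adjusted p 0.191 to 0.984), with 0.0469 in FoB against T2 with immunoglobulin genes removed, and of erythroid and platelet markers (8 of 17) 1 and 0, 0 and 3, 1 and 2 and 0 and 1 (adjusted p 0.0969 to 0.868). With 4 of 14 NK cell markers and 0 of 14 neutrophil markers measured, those lists were not tested. Camera called 36 of 104 list tests, 7 of them with an estimated correlation. Fry, which does not compare a list with other genes, called 55 lists but lost DNA replication (0.578) and interferon-stimulated genes (0.34) in T2 against T1, and ribosomal protein genes (0.34) and ribosome assembly factors (0.215) in FoB against T2. It was run on TPM as deposited, so in T2 against T1 it also counts the shift of most genes. The long reads measured fewer members, for example 6 of 30 for mitosis and 5 of 24 for sterol synthesis. They gained immediate early genes in T2 against T1 (0.0126), and lost mitosis (0.184), DNA replication (0.747), interferon-stimulated genes (0.0519), antigen presentation (0.3) and glycolysis (0.587) in T2 against T1, and sterol synthesis (0.65) and innate sensing (0.379) in MZ against T2. They also lost DNA replication (0.737) and ribosome assembly factors (0.816) in FoB against T2, and sterol synthesis (0.573), mitosis (0.287), innate sensing (0.485) and glycolysis (0.737) in MZ against FoB. Of 100 regroupings of the libraries, the real one included, 16 gave at least 36 camera calls. Subset differences can stay in such regroupings, so this gives no level of chance, and the number of lists called was given no weight. Member counts are not independent evidence either, because members move together. Their estimated correlation was 0.573 for ribosomal protein genes and 0.744 for interferon-stimulated genes. Of all tested genes 32.9%, 38.2%, 9.2% and 36.2% were called as deposited in the short reads, in the same order of comparisons.

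MZ and FoB share the T2 libraries in their comparisons with T2, so their calls and fold changes are not independent. In both comparisons 1030 genes were called, 307 higher in both, 453 lower in both and 270 in opposite directions. Independent lists of the same size would share 111 higher and 179 lower genes, counts that leave out the shared libraries. With separate T2 libraries for each comparison, 460 to 604 genes were called in both. Higher in both were Skap1, by 2.66 in MZ and 2.13 in FoB, Rhbdf1 by 3.87 and 2.03, Apoe by 2.11 and 1.67 and Traf1 by 2.56 and 1.53 on the log2 scale. Lower in both were Myb, by -2.30 and -2.80, Sox4 by -3.55 and -2.21, and Gfi1, a repressor of haematopoietic differentiation, by -2.32 and -2.20. In opposite directions were Plxnd1 (2.65 and -2.12), Rgs10 (4.01 and -1.62) and Mapk12 (-1.23 and 2.20). Skap1 and Gfi1 were chosen after their values were seen. Across all tested genes the correlation of both sets of fold changes was 0.289. Simulated groups gave 0.505 from the shared libraries alone, so the value of 0.289 says nothing of shared change. With separate T2 libraries for each comparison the correlation was 0.107 to 0.202. The sign was the same in 62.1% of all genes, against 66.7% in simulated groups. The covariance of the fold changes was 0.0678 against 0.024 in simulated groups, and 0.0301 to 0.0511 with separate T2 libraries.

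Long reads of the same RNA gave fold changes that correlated with those of the short reads across 5580 genes tested on both platforms. Pearson r was 0.72 for T2 against T1, 0.833 for MZ against T2, 0.53 for FoB against T2 and 0.815 for MZ against FoB, and Spearman rho was 0.555, 0.709, 0.374 and 0.676. Genes are not independent replicates, so no p-value was computed. In that order 186, 321, 16 and 373 genes were called on both platforms. The sign was shared by all of these except Uqcrc2, a subunit of respiratory complex III, in MZ against T2 (-0.21 in the short and 0.85 in the long reads). Without immunoglobulin genes r for T2 against T1 was 0.602. The median SE of a long-read log2 fold change was 0.37 to 0.38, against 0.14 in the short reads. In simulated data with 67 genes changed 2-fold, the long-read test recovered 22.4% to 28.4% of them and the short-read test 62.7% to 74.6%. The rates rest on that number of changed genes and on different genes per platform. They need not carry over to the data. Of 1.5-fold changes the long-read test recovered 1.5% to 7.5%.

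The immunoglobulin share fell from T2 to MZ (6.28 ± 0.56%) and to FoB (7.33 ± 0.50% of TPM, SD, n = 4, each exact permutation p = 0.0286, two-sided, adjusted p = 0.0381 against T2). Between MZ and FoB the test of that share did not pass (exact permutation p = 0.0571, two-sided, adjusted p = 0.0653). In the long reads the shares were 25.3 ± 3.85% of counts in T1, 8.06 ± 0.97% in T2, 5.76 ± 0.47% in MZ and 6.37 ± 0.40% in FoB. T1 libraries also differed from each other in which variable segments they held. Between T1 libraries 23.8% of the variable segment TPM differed on average (11.6% to 32.5%), against 6.29% between T2, 5.26% between MZ and 4.99% between FoB libraries, over 348 segments.

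**Figure D4:**
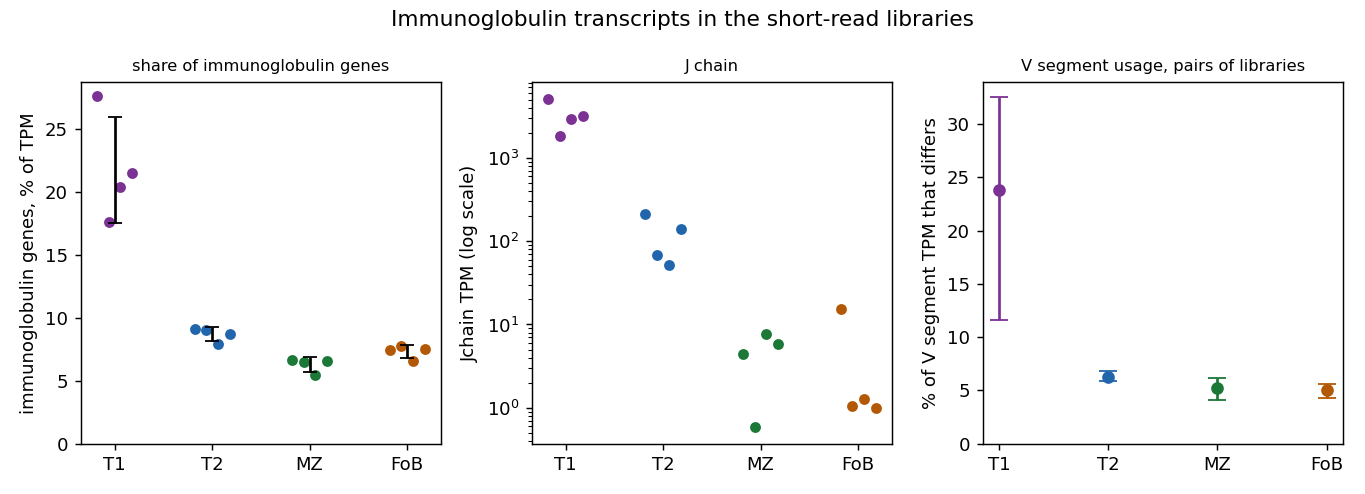
Percent of TPM from immunoglobulin genes and Jchain TPM (log axis) in each of the 16 short-read libraries, and the percent of variable segment TPM that differs between libraries of a subset (mean, lowest and highest pair). T1 libraries have the highest share (17.6% to 27.6%) and differ most from each other.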

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

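The tests of antibody-secreting cells, of replicate 3 and of ribosomal protein genes in this part were chosen after the patterns were seen, while the outlier checks and the regroupings of libraries were planned. A check of 144 groups of 4 libraries for a library far from the other 3 found 8, where about 7.2 would arise by chance at 5 in 100. In MZ replicate 3, immunoglobulin genes took 5.45% of TPM (6.50% to 6.65% in the others) and Cd93 read 0.418 TPM (0.101 to 0.145). In T2 replicate 3, immunoglobulin genes took 6.61% of long-read counts (8.45% to 8.65%). Jchain read 15.3 TPM in FoB replicate 1 (0.984 to 1.26). As list means of log2(TPM + 1) over that of all genes, the sort genes read 4.90 in T1 replicate 3 (5.22 to 5.25) and oxidative phosphorylation 3.20 in MZ replicate 3 (3.49 to 3.54). Mitosis read -0.0906 in T1 replicate 4 (-0.518 to -0.450), and immediate early genes 3.40 in FoB replicate 3 (2.69 to 2.76).

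Immunoglobulin and secretory transcripts were higher in T1 than in T2. A few genes taking most of the counts would lower all other genes of T1 alike, and so would not raise the secretory transcripts there. The mean of the 56 measured members of the folding and plasma cell lists over that of other genes changed by -0.55 (-0.548, SE 0.064) from T1 to T2 as deposited. Both lists had already been called lower in T2 on these libraries, so that value restates the pattern and is no separate test. T1 libraries differed in their variable segments 3.78 times as much as T2 libraries did, though the lambda segments alone differed by 3.31% and 2.48%. Antibody-secreting cells in the T1 libraries are a candidate source of that ratio, beside the abundant Igkc at 54930 TPM and Jchain at 3269 TPM in T1. The leading segment was Igkv5-39 in T1 replicates 1 and 3, at 10.3% and 13.7% of variable segment TPM. In T1 replicates 2 and 4 it was Iglv1, at 8.93% and 8.14%, which also led in every T2 and MZ library. Fewer cells per T1 library would also raise the ratio, and cell numbers are not given, so higher immunoglobulin transcription in all T1 cells as the whole cause cannot be told apart. The CD19 gate would remove plasma cells that have lost CD19, 19 of the 22 genes on the marker list are measured in these B cells, 7 are on another list, and higher secretory expression in some T1 cells stays open, untested.

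Libraries of replicate 3, the female mice, stood apart over the 4 subsets, with 2050 genes called (1626 higher, 424 lower). At most 4 autosomal genes were called with replicate 1, 2 or 4 set apart. Replicate 3 stayed among the other libraries in those fits and widened their spread, so few calls say little of processing by replicate number. Residuals of replicate 1 also correlated between subsets, at 0.12 to 0.26 in the short reads. Processing of each replicate number on its own therefore stays open. Of the 2050 genes 96.8% were autosomal, and 25 of 34 immediate early genes were higher and 3 lower, with Klf4 at 2.29, Egr1 at 1.48 and Cd69 at 1.56 on the log2 scale. Sex cannot be told apart from anything else that was particular to these 4 libraries, because no other female mice were measured. Depth stays open as well, since replicate 3 lay between other libraries in 1 subset and was the shallowest in 3.

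Cytosolic ribosomal protein genes were higher in MZ than in T2. Reads shared with named processed pseudogenes are argued against. For the 34 of 48 parents that have one in the tables, sums with the pseudogenes rose by a median log2 fold change of 0.61 (0.608), against 0.59 for these parents alone, and 34 of 34 sums rose. Other genes matched for expression and for the joined length of all annotated exons argue against a bias with that length. The median of these 96 genes was -0.08 (-0.075, quartiles -0.355 to 0.129). The joined length, a median of 1923.5 bases for the list, can exceed that of the transcripts expressed. A bias with transcript length therefore stays open. Pseudogenes not named after a parent were not summed, and higher expression in MZ cells stays a hypothesis, found and tested on the same data.

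In every comparison on both platforms the real grouping was the 1 of 35 with a count of changed genes as large. That is the smallest share that 35 groupings allow in 1 comparison, so chance is made less likely but not excluded. The other groupings mix both subsets on each side, which widens the spread and lowers their counts. For the short reads the real and the highest other counts were 5461 and 1 for T2 against T1, 6326 and 3 for MZ against T2, 1528 and 3 for FoB against T2, and 5993 and 536 for MZ against FoB. For the long reads they were 190 and 0, 337 and 0, 19 and 2, and 403 and 1. Over all 4 subsets 10216 genes stood against 426 in the highest of 99 other regroupings, and the 1030 genes changed in both MZ and FoB stood against 1. The number of lists called by camera did not stand out: 16 of 100 regroupings gave at least 36 and the highest other gave 43. Regroupings can hold a subset in unequal numbers on each side, so subset differences can stay in them. Their counts therefore do not give the level of chance, and chance is not excluded. The median of the other regroupings was 29 calls of 104 tests. With an estimated correlation 7 of the 36 calls were left, so adjusted p-values of single lists at the preset correlation cannot be taken at face value.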

How the results depend on the processing

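The leave-out fits of the lists, of the correlations between platforms and of the shared genes, and the mitochondrial share without immunoglobulin genes, were added after the data were seen, while the other alternatives were planned. For T2 against T1 the short reads gave 3388 genes with median-ratio scaling and 3078 with immunoglobulin genes removed, fewer because the shift of all other genes was taken out, and the long reads gave 57 with immunoglobulin genes removed. For FoB against T2 the long reads gave 29 genes with DESeq2, 48 with no low-count filter, 31 with a replicate block, 7 without replicate 3 of every subset and 1 with only the 2 groups fitted, against 19; the cause was not tested beyond the smaller number of libraries in the last 2. Leaving out each library gave 4190 to 5309, 5390 to 5918, 1086 to 1292 and 5060 to 5800 genes in the short reads and 148 to 180, 246 to 316, 7 to 27 and 288 to 402 in the long reads, in the order of the report, and 9447 to 10111 genes over all subsets. The replicate block gave 6519, 7090, 2052 and 6770 genes in the short reads, 225, 408, 31 and 508 in the long reads, and 37 lists. With the block the list calls lost were glycolysis in MZ against FoB (0.0664) and the sort genes in FoB against T2 (0.0608), and those gained were interferon-stimulated genes in FoB against T2 (0.00777) and MZ against FoB (0.0144) and immunoglobulin constant regions in MZ against T2 (0.0362). Residuals of equal numbers correlated above 0.1 in 18 of 24 pairs in the short reads, among them all 4 of T1 with T2 and all 4 of MZ with FoB, and in 10 of 24 in the long reads. Of 16 libraries, 13 and 7 correlated best with their own number. Whether the numbers mark pairs therefore stays open. The exact permutation tests took the libraries as unpaired, and with pairs the smallest p they can give would be larger.

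An estimated correlation left 7 of 36 list calls, fry gave 55 and long reads 17, and leaving out each library gave 34 to 39. Under fry, which does not compare a list with other genes, lists that camera left uncalled turned direction in T2 against T1: the sort genes (adjusted p = 0.000339), innate sensing (0.0144), migration and adhesion (0.00371), apoptosis and survival (0.00356) and B cell receptor signalling (0.0388). Fry was run on TPM as deposited, so it also counts the shift of most genes there. Without immunoglobulin genes the median log2 fold change of innate sensing went from 0.204 to -0.018, and of migration and adhesion from 0.131 to -0.091. That of apoptosis and survival went from 0.197 to 0.011, and of B cell receptor signalling from 0.145 to -0.077. These turns cannot be told apart from the scaling. The sort genes went from 0.08 to 0.622, with Ighm removed. In the long reads ribosomal protein genes turned direction in FoB against T2 (0.562). Over all list tests and settings 2328 results kept direction and side of the threshold, 62 lost and 48 gained a call and 6 reversed. For named genes these were 7767, 132, 3 and 0. With immunoglobulin genes left out of the total, the mitochondrial share gave adjusted p = 0.0653 for T2 against T1 and 0.0457 for MZ against T2 and MZ against FoB, against 0.0381 each.

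Between platforms r rose to 0.863, 0.874, 0.567 and 0.853 over genes with a mean long-read count of at least 20, and was 0.824, 0.898, 0.767 and 0.89 over genes called in the short reads, against 0.602 for T2 against T1 without immunoglobulin genes. Leaving out each replicate number gave 0.644 to 0.687, 0.781 to 0.798, 0.467 to 0.486 and 0.764 to 0.778. The 1030 genes changed in both MZ and FoB became 604, 480, 533, 460, 528 and 485 with T2 libraries split between the comparisons, which then shared no T2 library and had 2 each, and the cause of the lower counts was not tested. They were 744 to 1050 leaving out each library. Of simulated 1.5-fold changes 1.5% to 7.5% were recovered in the long reads.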

Other observations

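The permutation of list means in this part was chosen after the data were seen. Some genes known from plasma cells and from other lineages were higher in MZ cells. Prdm1, the regulator of plasma cell differentiation, read 9.67 ± 1.46 against 0.697 ± 0.119 TPM in MZ and T2, and Ighg3, the constant region of IgG3, read 38.6 ± 1.00 against 5.95 ± 0.904 TPM, with a log2 fold change of 2.88 ± 0.65 in the long reads. Prf1, which encodes perforin, rose by 2.61 ± 0.17, at 23.6 ± 1.25 against 3.18 ± 1.15 TPM, and the kinase gene Zap70 by 1.90 ± 0.19, at 7.56 ± 0.674 against 1.32 ± 0.518 TPM. The macrophage genes Mpeg1 and Cd68 rose by 1.89 ± 0.26 and 1.46 ± 0.20, at 17.4 ± 2.28 against 4.18 ± 1.98 TPM and 17.5 ± 3.6 against 5.74 ± 1.33 TPM, while Adgre1, which encodes F4/80, changed by -1.66 ± 0.14. Of regulators of RNA decay, Zc3h12c (ENSMUSG00000035164, chromosome 9, 52111344 to 52168572) rose by 3.39 ± 0.16, at 33.4 ± 4.99 against 2.28 ± 0.575 TPM, and by 3.42 ± 0.63 in the long reads, and Zfp36l2 changed by -1.74 ± 0.24. Other plasma cell genes were lower, Sdc1 by -2.57 ± 0.20 and Jchain by -4.44 ± 0.71, and on the list of antibody-secreting, B-1 and germinal centre markers 4 members rose and 9 fell.

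Some of the named genes are neighbours, a point noticed after their values were seen. Il9r (chromosome 11, 32187541 to 32200279) and Rhbdf1 (32209585 to 32222300) were both higher in FoB and in MZ than in T2, Il9r by 1.53 and 3.61 and Rhbdf1 by 2.03 and 3.87 on the log2 scale. Wfdc17 (chromosome 11, 83703991 to 83706268) changed by -4.38 ± 0.35 in MZ against T2, and Wfdc21 (83746940 to 83752642) was listed at 0 in every MZ library. The strand setting of the short-read tables is not given in the sources used here.

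Processed pseudogenes took 7.34 ± 2.45% of long-read counts and 4.37 ± 0.71% of TPM (SD, n = 16 libraries). The pseudogene Rps6-ps4 (chromosome 2, 75191073 to 75191822) held 5004 ± 2440 long-read counts, against 1959 ± 960 for its parent Rps6. In TPM the pseudogene stood at 135 ± 44.2 and the parent at 279 ± 89.9. Gm37376 (chromosome 19, 5801941 to 5802393, plus strand) lies within Malat1 (5795690 to 5802672, minus strand). It held 5232 ± 1860 long-read counts and was listed at 0 in the short-read tables, while Malat1 held 1024 ± 483 counts and 3332 ± 976 TPM. These genes were chosen after their values were seen.

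The mean of each list was compared between groups over the 70 groupings of 8 libraries. Of 104 list tests 50 reached the smallest exact permutation p of 0.0286, among them 32 of the 36 called by camera. After adjustment over 104 tests these stood at 0.0595, which follows from the smallest p that 4 against 4 libraries allow and from the number of tests that reached it, so a miss of 0.05 says nothing of the 32 calls. The other 4 calls missed the smallest p before adjustment: interferon-stimulated genes in T2 against T1 (0.0857), ribosome assembly factors (0.0857) and ribosomal protein genes (0.143) in FoB against T2, and ribosomal protein genes in MZ against FoB (0.0571).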
